A study of Homo sapiens with 18 samples.

How the data were processed

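Total RNA of human tissue was measured on Affymetrix GeneChip expression arrays, 1 array per sample. Per the labels, 5 arrays hold post-mortem prefrontal cortex (called brain here), 5 hold normal liver, 4 hold colon tumor and 4 hold normal colon. The group and replicate number of each sample were taken from its title. The series text names 5 individuals as the source of both brain and liver and calls the colon tumors and normals matched. It gives genome-wide DNA methylation data of these samples as the reason for choosing them; those data were not analysed here.

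The values are RMA expression values on the log2 scale as the authors deposited them. RMA corrects background, quantile-normalizes arrays and summarises the probes of a probe set; it is named in the submitters' processing notes without a version. The genome build and the probe annotation behind the values are not given in the sources used here. The colon columns were filled for 54675 probe sets. The brain and the liver columns were filled for the same 22277 probe sets, although the liver columns lie in the larger table, where 32398 rows were empty for them. The array type behind the liver columns was therefore taken from the values and not from the table that holds them.

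Which arrays were normalized together was read from exactly equal values, which RMA produces between arrays of one run. Brain and liver arrays shared 60 such values over 25 pairs of arrays (2.4 per pair, as many as within liver but fewer than the 7.1 within brain), and colon arrays shared 20.25 per pair among themselves. Colon arrays shared 0 with brain or liver arrays over 80 pairs. The higher number within brain was not explained. Brain and liver were tested against each other because they shared values at all, and tests of brain or liver against normal colon, which had been planned only for values normalized together, were not made. All columns of per-sample values were matched to a sample.

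Probe sets were named from the platform annotation supplied with the value tables, with symbols checked against a RefSeq gene table of assembly GRCh38.p14, which changed 0 symbols. Of the colon probe sets, 41097 had 1 gene symbol, 1801 had several and 11777 had none. For brain and liver these numbers were 19071, 1043 and 2163. Each gene was represented by the probe set with the highest mean among those with exactly 1 symbol. Y-linked genes and XIST were left out, 35 on the colon arrays and 24 on the others, which left 19740 and 11939 genes. No filter on low values was applied, and the tables give no detection calls, so changes of genes near the floor of the arrays are compressed. For arrays there is no read depth; the number of arrays limits the precision.

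Each comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, 2 groups per fit, no covariate). P-values were adjusted by the Benjamini-Hochberg method over all genes of the comparison, with a threshold of 0.05. A gene is called higher, lower, risen or fallen here only when it passed that threshold. Gene lists, 25 for the colon and 27 for brain and liver, were written from textbook knowledge before the data were examined, as were the tests, the main settings and the rule for naming genes. List shifts were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of each comparison, and again with an estimated correlation and with fry, which asks whether the members move on balance one way and does not compare them with other genes. Lists overlap in part, and lists with fewer than 5 measured members were not to be tested. Counts "adjusted over the list alone" repeat the adjustment within a list. Errors of log2 changes are moderated standard errors (SE), and those of group means are standard deviations (SD).

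Named genes are the 10 largest rises and the 10 largest falls among called genes whose groups did not overlap. They also include up to 4 called members of each list by size of change, or up to 6 for the lists of methylation machinery, imprinted genes and genes reported as hypermethylated in colon cancer. Where no member of a list passed, up to 2 are given as values. Among the named genes, GNAS was the one with another probe set called in the opposite direction.

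Replicate numbers pair the samples: the series text gives the same individuals for brain and liver and matched colon samples, and the titles carry the numbers. This was checked with genes whose expression is known to vary between people, before fits were compared. Over 88 probe sets of 36 such genes, deviations from the group means correlated across genes at a mean of 0.573 for normal colon and tumor arrays of the same number and -0.199 for different numbers. That was the highest of all 24 pairings (exact one-sided permutation p = 0.042, the smallest possible). For brain and liver the means were 0.309 and -0.075 over 56 probe sets of 34 genes, the highest of 120 pairings (exact one-sided permutation p = 0.008, the smallest possible). In these genes 4 of 4 normal colon arrays but 3 of 5 brain arrays correlated best with the array of their own number. Over all probe sets, same-number correlations ranged from -0.099 to 0.252 for the colon and from -0.117 to 0.32 for brain and liver. Different-number correlations largely overlapped these, from -0.226 to 0.167 and from -0.289 to 0.239. The main fits have no block; fits with the replicate number as a block are given where they change a list's count or the call of a named gene or list.

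Arrays of a group were compared with each other before averaging. The most alike colon pair, normal colon 1 and 2, had a Pearson correlation of 0.9907 across probe sets and a log2 difference with an SD of 0.29. The other colon pairs had SDs of 0.36 to 0.62, though the most alike brain pair reached 0.24. Normal colon 1 and 2 also shared 135 identical values, against 28 to 90 in the other colon pairs. No array was treated as a copy of another in the main fits, but whether normal colon 1 and 2 are independent samples was not settled. In a check for mixed samples, 3 of 8 colon arrays and 0 of 10 brain and liver arrays carried transcripts that 1 donor's cells would not be expected to hold together. With a stricter limit this was 2 of 8. No sample was left out on this ground.

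The fits were tested on simulated arrays made from the real means and SDs with 200 changed genes. For colon tumor against normal colon (19740 genes), 49% of log2 changes of 1 and 88% of log2 changes of 2 were recovered, with 3 of 140 calls wrong. For brain against liver (11939 genes), the shares were 65% and 95%, with 11 of 171 calls wrong. Camera called 10 of 10 shifted lists in both, and 0 and 2 of 100 unshifted ones. The genes were simulated independently of each other. Members of the real lists moved together, with estimated correlations such as 0.658 (cell cycle) and 0.871 (secreted hepatocyte proteins). The simulation therefore does not test how often camera wrongly calls such lists. At the preset correlation, other splits of the arrays that called 0 genes shifted up to 18 colon and 22 tissue lists.

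The overlap of the gene calls was tested with Fisher's exact test, two-sided, over genes tested in both comparisons, and against 10000 random gene lists matched on mean expression in 20 bins. Alternatives were a replicate block, repeated quantile normalization, median centring, a filter at the 40th percentile of each array, the mean of all probe sets, probe sets without the suffixes that mark shared probes, a trended robust prior, a required change over 2-fold, and leaving out each array in turn. Chosen after seeing the data were a fit with normal colon 1 and 2 averaged, a fit without liver 2 and 3, a fit of each comparison with the 3′ minus 5′ difference of GAPDH as a covariate, and matched lists for the alternatives of the overlap. P-values of the overlap alternatives are unadjusted.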

Results

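The series holds RNA profiles of 5 prefrontal cortex, 5 liver, 4 colon tumor and 4 normal colon samples. Its design implies a comparison of tumor with matched normal colon and a comparison of normal tissues, in samples that also have DNA methylation data. Array medians lay between 3.81 and 3.93 on the log2 scale on the colon arrays and between 5.89 and 6.02 on the brain and liver arrays, so levels were compared only within each set. Mean correlations of an array with the others of its group were 0.959 to 0.979 in normal colon, 0.963 to 0.970 in tumor, 0.949 to 0.981 in brain and 0.884 to 0.945 in liver. The series text gives 5 individuals for brain and liver but no number of donors for the colon samples, so colon p-values measure the spread between these samples, which may be partly technical.

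A measure of RNA quality set the groups apart in both comparisons. The log2 difference between the 3′ and the 5′ control probe sets of GAPDH, which grows when RNA is degraded or copied incompletely, was 0.55 ± 0.36 (SD, n = 5) in brain and 1.90 ± 0.38 (SD, n = 5) in liver. It was 0.93 ± 0.20 (SD, n = 4) in normal colon and 0.63 ± 0.11 (SD, n = 4) in colon tumor, where the highest value was 0.694 and the lowest in normal colon 0.741. The same difference for ACTB did not separate the colon groups (1.21 to 2.04 in tumor). Brain 1 had the highest value of the brain arrays (1.16) and liver 5 the lowest of the liver arrays (1.29).

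**Figure D1:**
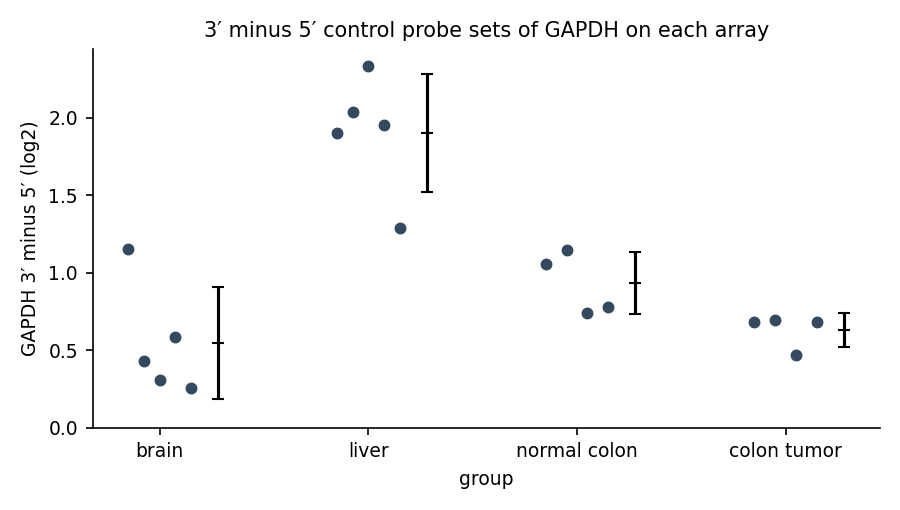
Log2 difference between the 3′ and 5′ control probe sets of GAPDH (vertical axis) on each array of the 4 groups (horizontal axis). Points are arrays, and bars beside them give the mean ± SD; all 5 liver arrays, from 1.29 to 2.34, lie above the highest brain array at 1.16.

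Colon tumors differed from normal colon in 877 of 19740 genes, 483 higher and 394 lower. In the fit with the replicate number as a block, 281 of the 483 and 262 of the 394 stayed called. The largest rise was in CEMIP, which encodes a hyaluronan-binding protein, 27.1-fold higher in tumor (log2 change 4.76 ± 0.64 (SE, n = 4 and 4), adjusted p = 0.00826). CLDN1, a tight junction protein, was 12.7-fold higher (3.66 ± 0.24, adjusted p = 0.000675), and TGFBI, an extracellular matrix protein, 12-fold higher (3.58 ± 0.41). The largest falls included CA1, a carbonic anhydrase of surface colonocytes, 50.8-fold lower (-5.67 ± 1.06, adjusted p = 0.0245), CLDN8, 29.2-fold lower (-4.87 ± 0.63), and GCG, which encodes proglucagon, 27.2-fold lower (-4.76 ± 0.45, adjusted p = 0.00254). Among the 10 largest rises were also FOXQ1 (19.8-fold), CLDN2 (12.7-fold), AZGP1 (11.2-fold), TCN1 (10.5-fold), CFI (9.65-fold), AXIN2 (9.45-fold) and ASCL2 (9.26-fold). The 10 largest falls were completed by SI (19.8-fold), ADH1B (18-fold), SFRP2 (17.8-fold), CA2 (15.6-fold), CXCL12 (13.6-fold), ACTG2 (13.2-fold) and B3GNT7 (13.1-fold). For 3 of the 10 falls the tumor mean, and for 5 of the 10 rises the normal colon mean, lay below the lowest array median, where changes are compressed.

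The number of calls depended on single arrays and on the covariate for RNA quality. With the 3′ minus 5′ difference of GAPDH as a covariate, which separates the colon groups, 19 genes were higher and 33 lower. Of the 877 genes 48 stayed called, 13 of the 67 named genes among them, and all 877 kept their direction. The 13 were CLDN1, ASCL2, APCDD1, SOX4, MEST, ADH1B, CXCL12, ADAMDEC1, TPH1, TAGLN, CNN1, TPSB2 and EFEMP1. The median share of the change left was 0.965, while the median SE rose from 0.218 to 0.309. Without normal colon 2 there were 87 higher and 123 lower genes, without normal colon 1 174 and 181, and without normal colon 3 608 and 754. The higher genes fell to 188 without normal colon 4, to 318 without tumor 2 and to 277 without tumor 3. With normal colon 1 and 2, the most alike pair of arrays, averaged as 1 replicate, 127 were higher and 153 lower. Of the 67 named colon genes past the threshold, between 7 (without normal colon 3) and 29 (without normal colon 2) lost their call with 1 array left out. The losses were 27, 21, 20, 14, 21 and 15 without normal colon 1, normal colon 4 and tumor 1, 2, 3 and 4, and 0 changed direction. Of the 20 largest changes, FOXQ1, CLDN2, CA2, SI and CA1 lost their call with at least 1 array left out (highest adjusted p 0.101, 0.123, 0.0522, 0.0771 and 0.0778), and CLDN2 also with the replicate block (adjusted p = 0.0542). No group overlap occurred in 12.6% of all genes, where chance gives 2.86%.

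Camera called the lists of differentiated colon epithelium lower in tumor, though most members of each did not pass and the calls were lost with an estimated correlation. Of 34 absorptive colonocyte genes, 7 fell, 0 rose and 27 did not pass (25 fell adjusted over the list alone), with a median log2 change of -2.52 (camera adjusted p = 5e-18, adjusted p = 0.165 with an estimated correlation). Besides CA1 and CA2, the bicarbonate transporter SLC4A4 fell 9.61-fold (-3.26 ± 0.35), and the steroid dehydrogenase HSD17B2 8.60-fold (adjusted p = 0.0244, up to 0.0747 with 1 array left out). With the replicate block 11 of the list were lower. Goblet cell genes had 1 of 18 lower (3 with the replicate block, 8 adjusted over the list alone), the membrane mucin MUC12 (-2.03 ± 0.34, adjusted p = 0.017, up to 0.0614 with 1 array left out). Their median was -1.26 (camera adjusted p = 1.91e-06, adjusted p = 0.197 with an estimated correlation). Of 14 enteroendocrine genes 4 were lower (8 adjusted over the list alone), with a median of -1.41 (camera adjusted p = 6.59e-07, adjusted p = 0.116 with an estimated correlation). They were GCG, the granule protein CHGB (-1.42 ± 0.16), TPH1, which makes the serotonin precursor (-3.03 ± 0.53, up to 0.0537 with 1 array left out), and PYY (-1.39 ± 0.32, up to 0.13). Normal colon 3 was the lowest normal array in CA1 (10.67), CA2 (11.27), SLC4A4 (9.10), HSD17B2 (6.74), MUC12 (10.55), GCG (6.47) and PYY (5.34). It was the highest in CHGB (5.52) and TPH1 (7.79).

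Camera called the lists of cell division, Wnt targets and the crypt higher in tumor. Of 34 cell cycle genes 19 rose, 0 fell and 15 did not pass (17 rose with the replicate block, 32 adjusted over the list alone), with a median log2 change of 1.28 (camera adjusted p = 8.09e-22, adjusted p = 0.165 with an estimated correlation). TPX2, a spindle protein, rose 3.94-fold (1.98 ± 0.29, adjusted p = 0.011), CCNB1 3.69-fold (1.88 ± 0.30, up to 0.0579 with 1 array left out), and the phosphatase CDC25B 6.58-fold (2.72 ± 0.53, up to 0.0959). The spindle checkpoint kinase TTK rose 4.33-fold (adjusted p = 0.0429, 0.0827 with the replicate block, up to 0.115 with 1 array left out). Of 21 Wnt target genes 9 rose and 12 did not pass (11 rose with the replicate block, 13 adjusted over the list alone), with a median of 1.39 (camera adjusted p = 3.9e-13, adjusted p = 0.00744 with an estimated correlation). AXIN2, a feedback inhibitor of the pathway, had a log2 change of 3.24 ± 0.40, the stem cell factor ASCL2 3.21 ± 0.36, APCDD1 3.09 ± 0.36 and SOX4 2.26 ± 0.15. A list of genes known to be high in crypts, polyps or colon tumors had 13 of 23 members higher (12 with the replicate block, 19 adjusted over the list alone), with a median of 2.54 (camera adjusted p = 3.2e-15, adjusted p = 0.0238 with an estimated correlation). It includes CEMIP, FOXQ1, CLDN2 and CLDN1. These were the lists whose calls held with an estimated correlation. With both the replicate block and an estimated correlation, the adjusted p was 0.116 for each. Ribosome biogenesis genes had 2 of 19 members higher (3 with the replicate block, 7 adjusted over the list alone), with a median of 0.71 (camera adjusted p = 1.67e-07, adjusted p = 0.224 with an estimated correlation). They were WDR12 (1.40 ± 0.20) and NHP2 (0.71 ± 0.14, adjusted p = 0.0643 with the replicate block and up to 0.0787 with 1 array left out).

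**Figure D2:**
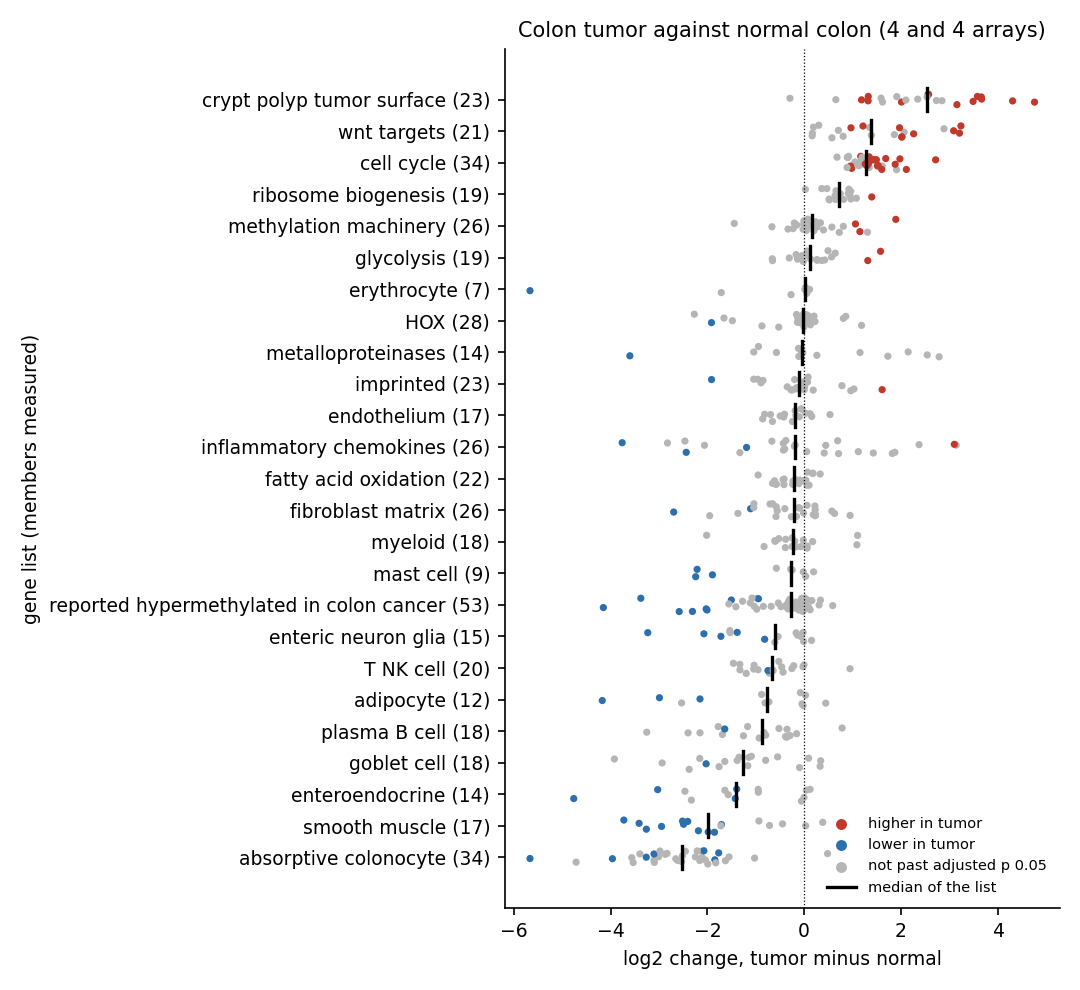
Log2 change of tumor minus normal colon (horizontal axis) for each measured member of the 25 gene lists (vertical axis, ordered by median). Points are genes, coloured when past an adjusted p of 0.05, and black bars are list medians, which run from -2.52 for absorptive colonocyte genes to 2.54 for crypt, polyp and tumor genes.

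Smooth muscle genes had the lowest median of the lists for non-epithelial cells. Mast cell and adipocyte genes could not be separated from them (medians 1.71 higher, 95% bootstrap interval over genes -0.19 to 2.39, and 1.22 higher, -0.43 to 2.36). Of 17 smooth muscle genes 11 fell, 0 rose and 6 did not pass (10 fell with the replicate block, 14 adjusted over the list alone), with a median log2 change of -1.98 (camera adjusted p = 4.52e-16, adjusted p = 0.116 with an estimated correlation). The muscle actin ACTG2 fell 13.2-fold (-3.73 ± 0.49), TAGLN 10.6-fold (-3.41 ± 0.28), the myosin MYH11 9.59-fold (-3.26 ± 0.38) and CNN1 7.72-fold (-2.95 ± 0.24). Mean log2 values of the list were 5.03 to 5.29 on the tumor arrays, 6.62 to 6.97 on normal colon 1, 2 and 3 and 7.85 on normal colon 4. Enteric neuron and glia genes had 5 of 15 members lower (3 with the replicate block, 8 adjusted over the list alone), with a median of -0.61 (camera adjusted p = 6.11e-07, adjusted p = 0.116 with an estimated correlation). Among them were the neuropeptide VIP (-3.23 ± 0.56, up to 0.0694 with 1 array left out), GPM6B (-2.07 ± 0.33, up to 0.0569), STMN2 (-1.72 ± 0.24) and CRYAB (-1.38 ± 0.24, adjusted p = 0.0507 with the replicate block and up to 0.0503 with 1 array left out). Of 9 mast cell genes 3 fell (2 with the replicate block, 3 adjusted over the list alone), the tryptases TPSB2 (-2.24 ± 0.25) and TPSAB1 (-2.21 ± 0.27) and CPA3 (-1.90 ± 0.36, adjusted p = 0.0511 with the replicate block and up to 0.0657 with 1 array left out). Their median was -0.28 (camera adjusted p = 0.000375, adjusted p = 0.189 with an estimated correlation). Adipocyte genes had 3 of 12 members lower (2 with the replicate block, 3 adjusted over the list alone), with a median of -0.77 (camera adjusted p = 0.000146, adjusted p = 0.116 with an estimated correlation). They were ADH1B (-4.17 ± 0.26), an alcohol dehydrogenase that fibroblasts also express, CFD (-2.99 ± 0.46) and FABP4 (-2.15 ± 0.43, adjusted p = 0.054 with the replicate block and up to 0.0683 with 1 array left out).

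Endothelial genes had 0 of 17 members past the threshold in limma (5 at an unadjusted p under 0.05, 1 lower adjusted over the list alone), with a median of -0.19; the largest differences were PECAM1 at -0.86 (adjusted p = 0.115) and CLDN5 at -0.82 (adjusted p = 0.056). Their shift had a camera adjusted p of 0.00441, 0.37 with an estimated correlation and 0.0589 without tumor 3. Of 26 fibroblast and matrix genes 2 fell (1 with the replicate block, 2 adjusted over the list alone), DCN (-2.70 ± 0.51, adjusted p = 0.0706 with the block and up to 0.0631 with 1 array left out) and FN1 (-1.11 ± 0.16). The median was -0.21 (camera adjusted p = 0.0273, adjusted p = 0.584 with an estimated correlation), and the call was lost without normal colon 3 (0.16), normal colon 4 (0.091) or tumor 1 (0.212), 3 (0.129) or 4 (0.111). Myeloid genes had 0 of 18 past the threshold in limma (3 at an unadjusted p under 0.05, 1 lower with the replicate block, 0 adjusted over the list alone), with a median of -0.22 (camera adjusted p = 0.0399, adjusted p = 0.478 with an estimated correlation). That call was lost without normal colon 3 (0.236), normal colon 4 (0.0626) or tumor 3 (0.182) or 4 (0.069). CD14 stood at -2.02 (adjusted p = 0.0614, 0.0378 with the replicate block) and LYZ at 1.10 (adjusted p = 0.54). T and NK cell genes had 1 of 20 lower (2 with the replicate block, 6 adjusted over the list alone), NKG7 (-0.75 ± 0.17, adjusted p = 0.0474, up to 0.135 with 1 array left out), with a median of -0.66 (camera adjusted p = 6.68e-07, adjusted p = 0.202 with an estimated correlation). B and plasma cell genes had 1 of 18 lower (1 adjusted over the list alone), TNFRSF17 (-1.64 ± 0.38, adjusted p = 0.0493, 0.0828 with the replicate block, up to 0.146 with 1 array left out), with a median of -0.88 (camera adjusted p = 1.62e-05, adjusted p = 0.202 with an estimated correlation). Of 7 erythrocyte genes 1 was lower (1 adjusted over the list alone), CA1, which colonocytes also express. That list had a median of 0.01, a mean of -1.06 and a camera direction downward (adjusted p = 0.0902, 0.0279 without normal colon 1). With fry the goblet cell list (adjusted p = 0.0576) and the T and NK (0.0576), B and plasma cell (0.0905), endothelial (0.215), myeloid (0.301) and fibroblast and matrix (0.511) lists were not called.

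Genes tied to DNA methylation were examined because the samples were chosen for their methylation data. Of 53 genes reported elsewhere as hypermethylated in colon cancer, 8 fell, 0 rose and 45 did not pass (4 fell with the replicate block, 8 adjusted over the list alone). Their median was -0.28 (camera adjusted p = 6.11e-07, adjusted p = 0.165 with an estimated correlation). The Wnt antagonists SFRP2 and SFRP1 fell 17.8-fold (-4.15 ± 0.55) and 5.99-fold (-2.58 ± 0.37), and the matrix protein EFEMP1 10.4-fold (-3.38 ± 0.33). SDC2 had a log2 change of -2.03 ± 0.33, TIMP3 of -2.31 ± 0.50 (adjusted p = 0.0914 with the replicate block, up to 0.101 with 1 array left out) and VIM of -2.01 ± 0.43 (0.0573 with the block, up to 0.0827 with 1 array left out). These genes fell beside the smooth muscle genes. SFRP1, SFRP2, EFEMP1, TIMP3 and SDC2 were highest on normal colon 4 (7.71, 9.38, 8.13, 7.73 and 6.70). TIMP3 and SDC2 were nearly as high on normal colon 3 (7.63 and 6.54), the normal array with the lowest smooth muscle mean (6.62). VIM was highest on normal colon 3 (11.18, against 9.47 to 9.93 on the other normal arrays). Of 26 genes placed on the list of methylation machinery, 3 rose and 23 did not pass (1 rose with the replicate block, 3 adjusted over the list alone). The list's median was 0.16 (camera adjusted p = 0.117, 0.0499 with the replicate block, 0.0237 without normal colon 3 and 0.0379 without tumor 4). When limma was run over probe sets instead of genes, 0 probe sets of each of the 3 risen genes passed. They were APOBEC1 (1.89 ± 0.43, up to 0.117 with 1 array left out), the de novo methyltransferase DNMT3A (1.15 ± 0.26, adjusted p = 0.0455, 0.0706 with the block, up to 0.119 with 1 array left out) and ZBTB33 (1.06 ± 0.24, adjusted p = 0.0476, 0.074 with the block, up to 0.132 with 1 array left out). Imprinted genes had 1 of 23 higher and 1 lower (2 and 1 with the replicate block, 4 and 4 adjusted over the list alone), and no shift as a list (median -0.11, camera adjusted p = 0.227). MEST rose 3.06-fold (1.61 ± 0.14, adjusted p = 0.00184), and NDN fell 3.77-fold (-1.92 ± 0.41, up to 0.12 with 1 array left out). Of 28 HOX genes 1 fell, HOXD13 (-1.92 ± 0.43, up to 0.136 with 1 array left out); adjusted over the list alone, 2 were higher and 4 lower. The HOX median was -0.03 (camera adjusted p = 0.15, 0.039 without normal colon 3).

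**Figure D3:**
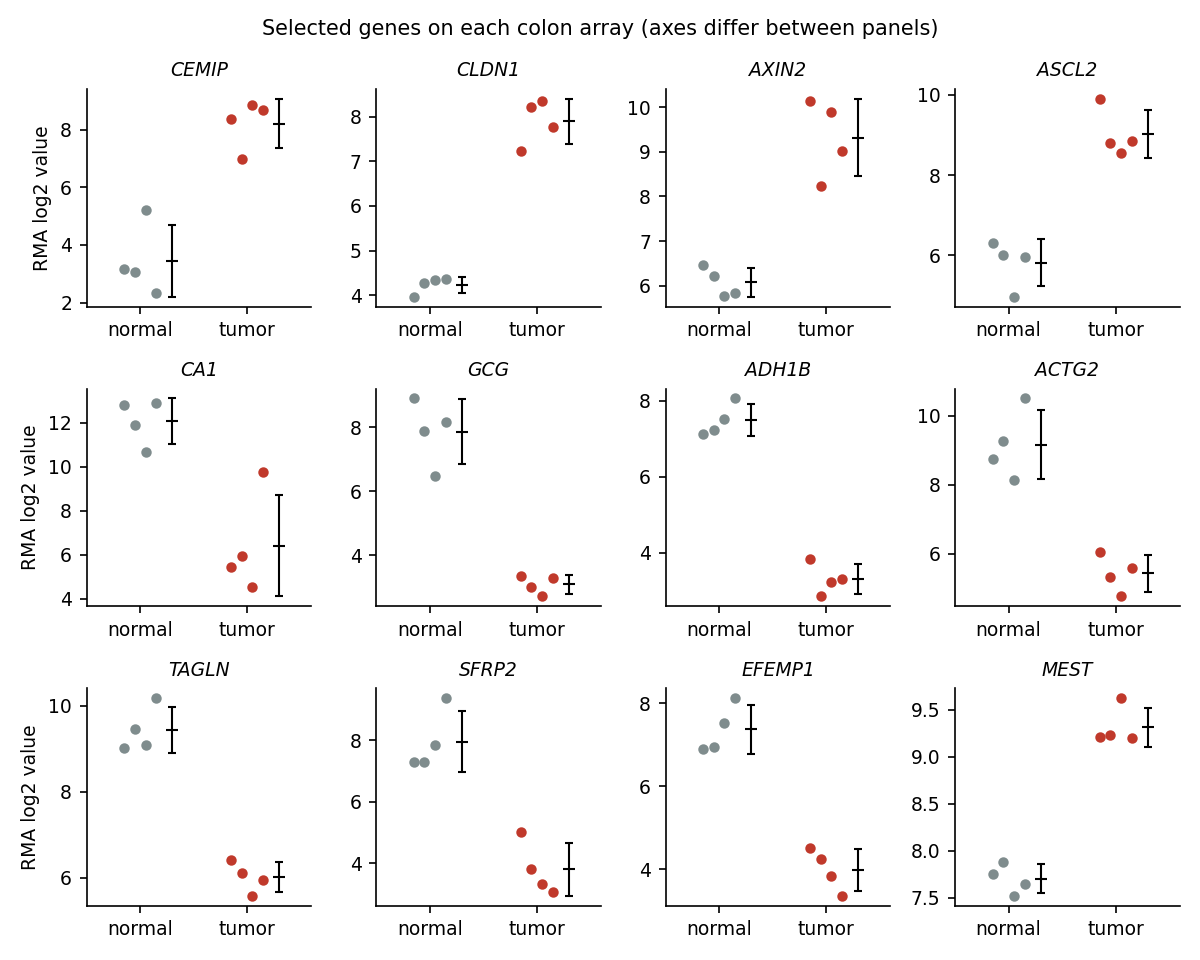
RMA log2 values (vertical axes, with ranges that differ between panels) of 12 named genes on the 4 normal colon and 4 tumor arrays. Points are arrays and bars beside them give the mean ± SD; the groups do not overlap in any panel, and CEMIP rises from a mean of 3.45 to 8.21 while ACTG2 falls 13.2-fold.

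Chemokine, protease and metabolic lists showed no shift as groups. Of 26 inflammatory and chemokine genes 1 rose and 3 fell (2 and 2 with the replicate block, 4 and 5 adjusted over the list alone), with a median of -0.19 (camera adjusted p = 0.284, 0.0313 without tumor 2). The neutrophil chemoattractant CXCL3 rose 8.60-fold (adjusted p = 0.0297, up to 0.101 with 1 array left out). CXCL12, a stromal chemokine, fell 13.6-fold (-3.76 ± 0.54), CCL21 5.42-fold (-2.44 ± 0.46, adjusted p = 0.05 after rounding and no longer called with the replicate block, up to 0.0714 with 1 array left out) and CCL23 2.28-fold (adjusted p = 0.0286, 0.0584 with the block, up to 0.0982 with 1 array left out). Metalloproteinases had 1 of 14 lower (2 with the replicate block, 1 higher and 2 lower adjusted over the list alone), ADAMDEC1 (-3.60 ± 0.38). Their median was -0.04 and their mean 0.30, with a downward camera direction (adjusted p = 0.563). Glycolysis genes had 2 of 19 higher (3 adjusted over the list alone), LDHB (1.58 ± 0.23) and PFKM (1.32 ± 0.24, up to 0.0809 with 1 array left out). Their median was 0.13 (camera adjusted p = 0.117, 0.0265 without normal colon 1 and 0.0347 without tumor 1). Of 22 fatty acid oxidation genes 0 passed in limma (2 at an unadjusted p under 0.05, 0 adjusted over the list alone), with ETFB at -0.95 (adjusted p = 0.549) and ACAA1 at -0.65 (adjusted p = 0.526). The median was -0.20 (camera adjusted p = 0.0724, 0.0413 with the replicate block, 0.0067 without normal colon 3 and 0.0063 without tumor 3).

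Brain and liver differed in 4570 of 11939 genes, 2551 higher and 2019 lower in brain. The largest rises were in TUBA1A, a neuronal tubulin, 113-fold higher in brain (log2 change 6.82 ± 0.43 (SE, n = 5 and 5), adjusted p = 5.93e-07), the glutamate receptor subunit GRIA2 (6.65 ± 0.15, adjusted p = 4.5e-10) and MBP, a protein of myelin (6.44 ± 0.46). They also included SYT1, GPM6A, KIF5C, CHN1, RGS4, SERPINI1 and GPM6B, with log2 changes between 6.06 and 6.37. Plasma protein genes led the falls: ALB, encoding albumin, was 685-fold lower in brain (-9.42 ± 0.16, adjusted p = 4.65e-11), APOC3 329-fold, APOA2 299-fold, SERPINA1 237-fold and ORM1 193-fold. ADH1B, APOH, CYP2E1, CYP2C8 and AHSG followed, from 157-fold to 131-fold. The 20 largest changes kept their calls with each array left out and with the replicate block. The lower group's mean was under the lowest array median for 9 of the 10 falls and 8 of the 10 rises, so these folds are compressed. With the 3′ minus 5′ difference of GAPDH as a covariate, 802 genes were higher and 759 lower. Of the 116 named genes past the threshold 79 stayed called and 7 changed direction without passing.

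Camera called the lists of neurons and glia higher in brain. Of 29 neuronal genes 26 rose and 3 did not pass (25 rose with the replicate block, 27 adjusted over the list alone), with a median log2 change of 3.28 (camera adjusted p = 2.97e-15, adjusted p = 0.217 with an estimated correlation). The neurofilament genes NEFM (5.95 ± 0.61) and NEFL (5.64 ± 0.50) were among them. Interneuron genes had 13 of 15 higher (13 adjusted over the list alone; camera adjusted p = 2.52e-06, adjusted p = 0.263 with an estimated correlation), among them CCK (5.16 ± 0.56), the GABA-synthesising enzyme GAD1 (4.41 ± 0.51), CNR1 (3.65 ± 0.30) and SST (3.32 ± 0.45). Of 16 oligodendrocyte genes 13 rose and 1 fell (13 and 1 adjusted over the list alone; camera adjusted p = 6.47e-06, adjusted p = 0.274 with an estimated correlation); ENPP2 was 13.6-fold, MAL 6.06-fold and MAG 6.01-fold higher. Astrocyte genes had 9 of 16 higher and 2 lower (9 and 2 adjusted over the list alone; camera adjusted p = 0.0199, adjusted p = 0.472 with an estimated correlation). GFAP, the astrocyte intermediate filament, was 55.7-fold higher (5.80 ± 0.44), GJA1 24.4-fold, SLC1A3 15.3-fold and S100B 10.9-fold. Oligodendrocyte precursor genes had 4 of 8 higher (5 with the replicate block, 5 adjusted over the list alone; camera adjusted p = 0.0214, adjusted p = 0.416 with an estimated correlation), PTPRZ1 (4.76 ± 0.28), OLIG2 (1.89 ± 0.30), VCAN (1.01 ± 0.28) and NKX2-2 (1.08 ± 0.33, up to 0.0644 with 1 array left out). Of 19 synaptic and ion channel genes 12 rose and 1 fell (12 and 2 adjusted over the list alone; camera adjusted p = 3.09e-05, adjusted p = 0.282 with an estimated correlation), led by the calcium channel ITPR1 (4.02 ± 0.25) and the sodium channel SCN1A (3.22 ± 0.44). Neural transcription factors had 12 of 18 higher (13 adjusted over the list alone; camera adjusted p = 3.89e-05, adjusted p = 0.217 with an estimated correlation), with MEF2C (5.42 ± 0.48) and MYT1L (5.19 ± 0.36) highest. With the GAPDH covariate in limma NEFM (3.515, adjusted p = 0.0761), CCK (2.77, 0.106), GAD1 (2.92, 0.111), SST (2.10, 0.197) and SCN1A (1.86, 0.227) were no longer called. NEFL stayed called at a smaller change (4.44). The named astrocyte and oligodendrocyte genes stayed called at larger changes, such as GFAP (5.80 to 8.04), MBP (6.44 to 8.51), GJA1 (4.61 to 6.95) and MAG (2.59 to 4.80). Brain 1, which has the largest GAPDH difference in brain, was the lowest brain array in 26 of the 29 neuronal genes. It was the highest in 14 of 16 astrocyte and 13 of 16 oligodendrocyte genes. The covariate cannot separate RNA quality from what else sets brain 1 apart.

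Camera called the lists of hepatocyte function lower in brain. All 23 measured genes of secreted hepatocyte proteins fell (23 adjusted over the list alone; median -6.25, camera adjusted p = 7.39e-19, adjusted p = 0.217 with an estimated correlation). So did all 27 of coagulation and complement (27 adjusted over the list alone; median -3.75, camera adjusted p = 7.99e-16, adjusted p = 0.233 with an estimated correlation), such as F9 (-6.67 ± 0.33) and KNG1 (-5.86 ± 0.45). All 17 genes of urea and amino acid metabolism fell (17 adjusted over the list alone; median -3.01, camera adjusted p = 4.58e-10, adjusted p = 0.26 with an estimated correlation), AGXT by 102-fold and the urea cycle enzyme CPS1 by 31.8-fold. Of 21 cytochrome P450 genes 18 fell and 2 rose (19 and 2 adjusted over the list alone; camera adjusted p = 3.91e-09, adjusted p = 0.217 with an estimated correlation); CYP2E1 was 136-fold and CYP3A5 80.1-fold lower. Bile acid and transport genes had 14 of 15 lower (14 adjusted over the list alone; camera adjusted p = 3.91e-09, adjusted p = 0.217 with an estimated correlation), with AKR1D1 at -6.57 ± 0.42 and the transporter SLCO1B3 at -4.53 ± 0.48. Gluconeogenesis and glycogen genes had 11 of 14 lower and 2 higher (11 and 2 adjusted over the list alone; camera adjusted p = 0.000601, adjusted p = 0.307 with an estimated correlation), the glucose transporter SLC2A2 by 69.4-fold and PCK1 by 36.1-fold. Acute phase genes had 11 of 13 lower (12 with the replicate block, 11 adjusted over the list alone; camera adjusted p = 1.17e-07, adjusted p = 0.217 with an estimated correlation), among them FGB (-6.93 ± 0.43) and HP (-6.88 ± 0.66). Of 9 hepatic transcription factors 8 fell (9 adjusted over the list alone; camera adjusted p = 2.52e-06, adjusted p = 0.217 with an estimated correlation), with CEBPA 17.2-fold lower (-4.11 ± 0.22).

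**Figure D4:**
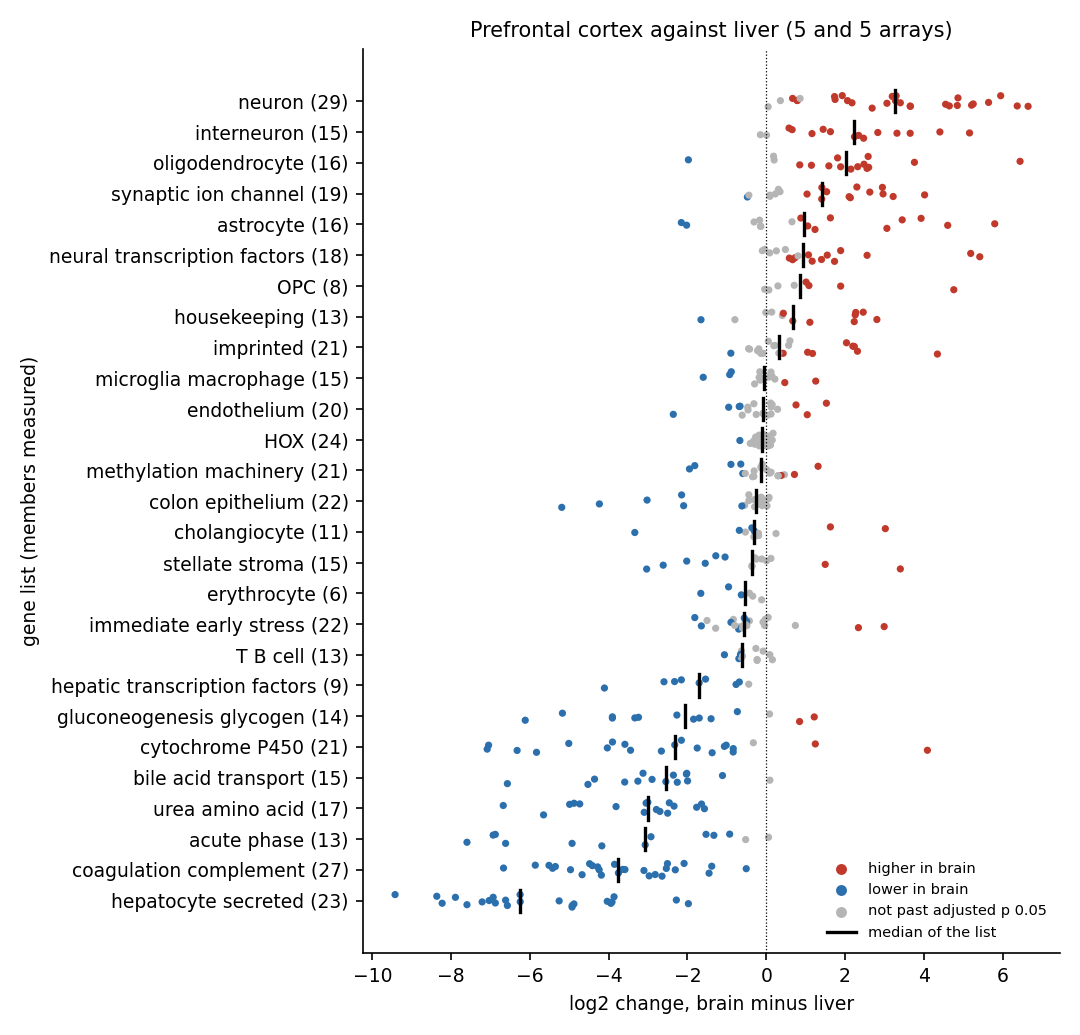
Log2 change of brain minus liver (horizontal axis) for each measured member of the 27 gene lists (vertical axis, ordered by median). Points are genes, coloured when past an adjusted p of 0.05, and black bars are list medians, from -6.25 for secreted hepatocyte proteins to 3.28 for neuronal genes.

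Lists of microglia, endothelial, stellate and cholangiocyte genes were not called by camera; fry called the cholangiocyte list lower (adjusted p = 0.0143). Microglia and macrophage genes had 2 of 15 higher and 3 lower (2 and 3 adjusted over the list alone; camera adjusted p = 0.597), with CX3CR1 at 1.26 ± 0.35 and LYZ at -1.60 ± 0.41. Endothelial genes had 3 of 20 higher and 4 lower (3 and 4 adjusted over the list alone; camera adjusted p = 0.483): VWF was 2.06-fold higher, and FCN3, a lectin of liver sinusoids, 5.13-fold lower in brain. Stellate cell and stroma genes had 2 of 15 higher and 6 lower (2 and 7 adjusted over the list alone; camera adjusted p = 0.0623, 0.0469 without brain 3 and 0.034 without liver 5), with COL3A1 at -3.04 ± 0.36 and THY1, also a neuronal surface protein, 10.6-fold higher. Cholangiocyte genes had 2 of 11 higher and 4 lower (2 and 2 with the replicate block, 2 and 4 adjusted over the list alone; camera adjusted p = 0.161), with SPP1, a secreted phosphoprotein that glia also express, at 3.02 ± 0.48 and ANXA4 at -3.34 ± 0.23. Erythrocyte genes had 3 of 6 lower (3 adjusted over the list alone), HBB by 3.16-fold. The list's camera adjusted p was 0.0415, 0.472 with an estimated correlation, 0.0503 without brain 4, 0.0961 without liver 2 and 0.0554 without liver 3. T and B cell genes had 4 of 13 lower (5 with the replicate block, 4 adjusted over the list alone), CCL5 by 2.09-fold. The camera adjusted p was 0.0378, 0.472 with an estimated correlation, 0.0503 without brain 4, 0.0534 without liver 1 and 0.0966 without liver 2. Repeated quantile normalization raised the adjusted p of both lists to 0.0518, and fry gave 0.0547 for the T and B cell list. With the GAPDH covariate CX3CR1 (1.56), LYZ (-0.91), FCN3 (-1.08), HBB (-0.73) and CCL5 (-0.37) were no longer called. COL3A1 also lost its call (adjusted p = 0.0698), at a change of -2.545 while its SE rose from 0.36 to 0.82. A list of colon epithelium genes had 6 of 22 lower (6 adjusted over the list alone; camera adjusted p = 0.00285, adjusted p = 0.263 with an estimated correlation). Its largest falls were FABP1 (-5.19 ± 0.69), CDH1 (-4.24 ± 0.47), KRT18 (-3.03 ± 0.43) and KRT8 (-2.15 ± 0.32), which hepatocytes also express.

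Of 13 housekeeping genes 8 were higher in brain and 1 lower (8 and 2 with the replicate block, 8 and 1 adjusted over the list alone; camera adjusted p = 0.0188, adjusted p = 0.472 with an estimated correlation), beside the larger 3′ minus 5′ difference of the liver arrays. HPRT1 was 7.01-fold, PGK1 5.51-fold, GAPDH 4.83-fold and YWHAZ 4.79-fold higher in brain, a direction kept with repeated quantile normalization and with centred medians. With the GAPDH covariate HPRT1 and PGK1 changed direction (-0.45 ± 0.84 and -0.40 ± 0.70) and did not pass. GAPDH (0.95) and YWHAZ (0.50) were no longer called. For GAPDH this shows little, because the covariate is computed from probe sets of GAPDH itself. Immediate early and stress genes had 2 of 22 higher and 6 lower (2 and 9 with the replicate block, 2 and 6 adjusted over the list alone), with HSPH1 at 2.99 ± 0.44, EGR3 at 2.34 ± 0.31 and GADD45A at -1.81 ± 0.32. HSPH1 (1.06) and EGR3 (1.41) lost their calls with the covariate. Their camera adjusted p was 0.0548, 0.0259 with the replicate block, 0.0322 with repeated quantile normalization, and 0.0298, 0.0194 and 0.0368 without brain 1, liver 2 and liver 3.

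Camera called the list of imprinted genes higher in brain: 8 of 21 rose and 1 fell (8 and 2 with the replicate block, 9 and 2 adjusted over the list alone; median 0.32, camera adjusted p = 0.0298, adjusted p = 0.217 with an estimated correlation). PEG3 rose 20.3-fold (4.35 ± 0.25), NDN 4.98-fold (2.32 ± 0.29), GNAS 4.71-fold, MEG3 4.59-fold and CDKN1C 4.10-fold. For GNAS 7 probe sets were called higher in brain and 1 lower. Methylation machinery genes had 3 of 21 higher and 5 lower (2 and 5 with the replicate block, 3 and 5 adjusted over the list alone). Their camera adjusted p was 0.367, while fry, which does not compare them with other genes, gave a downward shift (adjusted p = 0.000496). EZH1, a histone methyltransferase, was 2.49-fold and the maintenance methyltransferase DNMT1 1.64-fold higher in brain, while the glycosylase MBD4 was 3.86-fold lower (-1.95 ± 0.14). Of 24 HOX genes 1 was lower in brain (1 adjusted over the list alone), HOXB2 (-0.67 ± 0.16; camera adjusted p = 0.272 for the list). With the GAPDH covariate NDN (2.15, adjusted p = 0.0617), GNAS (0.57, 0.674), DNMT1 (0.31, 0.571) and HOXB2 (-0.13, 0.856) were no longer called, while PEG3 (3.64), MEG3, CDKN1C, EZH1 and MBD4 were.

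Genes that differed between tumor and normal colon were not clearly over-represented among those that differed between brain and liver. Of 679 tumor-changed genes measured in both comparisons, 283 also differed between the tissues (odds ratio 1.16, 95% interval 0.99 to 1.36, Fisher's exact test p = 0.0616, adjusted 0.103), and random lists matched on expression gave 279.8 on average (permutation p = 0.804). In 8 of 12 alternatives the unadjusted Fisher's exact p was under 0.05: with a change over 2-fold required as well (odds ratio 1.7, p = 7.74e-07), with the mean of all probe sets (1.28, p = 0.00437), and with the replicate block (1.2, p = 0.0405). The others, again by Fisher's exact test, were without normal colon 2 (1.6, p = 0.00251), normal colon 3 (1.24, p = 0.00087), tumor 1 (1.2, p = 0.0371), tumor 2 (1.42, p = 0.000205) or tumor 3 (1.24, p = 0.0331). Against matched random lists the unadjusted permutation p was under 0.05 in 3 of the 12. These were with a change over 2-fold (0.0001, the smallest possible) and without normal colon 2 (0.0152) or tumor 2 (0.0094). By direction, 89 of 315 genes lower in tumor were higher in brain (odds ratio 1.47, Fisher's exact test adjusted p = 0.0168) and 70 were higher in liver (1.42, adjusted p = 0.0363). Matched random lists gave 69.8 and 54.8 (permutation p = 0.0082 and 0.0217). Of 364 genes higher in tumor, 74 were higher in brain (odds ratio 0.94, adjusted p = 0.65) and 50 higher in liver (0.78, adjusted p = 0.129). Here matched random lists gave more, 87.5 and 67.3 (permutation p = 0.103 and 0.0192), so the count shared with liver lay below them. The permutation p-values are unadjusted. Genes are not independent replicates, and the difference between the directions was not tested.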

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

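Chosen only after the result was seen were the test that sets smooth muscle against the other cell-type lists, its restriction to bright members, the test with the GAPDH covariate, and the ranks of brain 1 by gene list.

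Smooth muscle genes were lower in every colon tumor, with list means of 5.03 to 5.29 against 6.62 to 7.85 in normal colon. A lower share of all non-epithelial cells would move their markers alike, but the endothelial median lay 1.8 above the smooth muscle median (95% bootstrap interval 0.76 to 2.39, on the log2 scale) and the myeloid median 1.76 above it, while the intervals of the mast cell and adipocyte lists included 0. Among members bright in normal colon, 6 endothelial and 11 smooth muscle genes, the endothelial median was still 2.07 higher (1.43 to 2.88). These intervals come from resampling the genes of a list, not the samples, so they do not measure the spread between tumors. For these samples alone, the medians argue against an equal loss of all non-epithelial cells as the whole explanation. A different amount of muscle wall in the samples may contribute, and within groups the smooth muscle genes deviated together. Their mean pairwise correlation was 0.55 (0.188 without normal colon 4), at percentiles 100 and 99.7 of 1000 random lists matched on expression. Genes of the same cell type can move together for other reasons, so this test cannot tell muscle content from a change within muscle cells. A change of the muscle cells of the tumor itself was not tested and stays open.

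Of 53 genes reported as hypermethylated in colon cancer 8 were lower in tumor (4 with the replicate block), and the camera call of the list was lost with an estimated correlation (adjusted p = 0.165). Fewer muscle and stromal cells could lower them too, and this could not be decided: over the 8 arrays the median correlation of the called members' within-group deviations with the smooth muscle score was 0.287, at percentile 92.5 of equally many other genes lower in tumor. The members differed: SFRP1 had 0.927, SFRP2 0.722, EFEMP1 0.579, SDC2 0.294, TIMP3 0.28, SLIT2 0.193, HIC1 -0.232 and VIM -0.279. Methylation of these genes was not analysed here and stays open as an explanation.

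Liver arrays had larger 3′ minus 5′ differences than brain arrays, so poorer RNA of the liver samples could enter the differences between the tissues. With that difference as a covariate, 1361 of the 4570 genes (29.8%) stayed called in the same direction and 87.4% kept their direction. The covariate rests on GAPDH alone, and its values do not overlap between the groups (brain up to 1.16, liver from 1.29). The calls that stayed therefore cannot exclude RNA quality as a cause. For the 3209 calls that ended, the median share of the change left was 0.598, the median SE rose from 0.201 to 0.406, and 17.9% changed direction. In the arrays closest in this measure, brain 1 and liver 5, genes called from the other arrays showed a median of 0.601 of their change, and 76.7% of 4990 kept their direction. That pair cannot separate RNA quality from what else sets brain 1 apart, and the size of the contribution stays open beside the difference in tissue.

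For colon tumor against normal colon, 1 of the 35 splits of the arrays, the real one, called as many as 877 genes. The highest other split called 0, so the real split stood alone among the 35. Most splits do not keep to the matched pairs, however. The 8 that part every pair, with 0 as the highest other, are too few to exclude chance. For the colon lists 5 of the 35 splits shifted as many as the real 17, with 18 as the highest other. Chance is therefore not excluded for the number of lists. Even among the splits that part every pair, another one shifted 17 lists while calling 0 genes. For brain against liver, 1 of 100 drawn splits, the real one, called as many as 4570 genes, with 2 as the highest other. Most of these splits do not keep to the pairs either. The 9 that part every pair, with 0 as the highest other, are again too few to exclude chance. For the tissue lists 6 of 100 splits shifted as many as the real 20, with 22 as the highest other. Chance is not excluded for that number either. Here too, another split that parts every pair shifted 20 lists while calling 0 genes. Camera at the preset correlation thus called many lists in splits without gene calls.

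Of 394 groups of values examined, 37 (9.39%) had 1 array far from the others by Dixon's test, where chance gives about 1 in 20. Brain 1 accounted for 23. Its mean correlation with the other brain arrays was 0.949, against 0.9771 to 0.9809 for those, and it was low in neuronal and synaptic genes: SYT1 9.60 (others from 12.17), CHN1 10.52, RGS4 9.55, SERPINI1 9.12, NEFM 7.76, NEFL 8.73, CCK 7.55, GAD1 6.93, THY1 9.11, SCN1A 5.84 and GLRB 5.27. The same array was low in HPRT1 (6.903), PGK1 (8.73), GAPDH (12.92), HSPH1 (8.05), CX3CR1 (6.58), PEG3 (9.33), NDN (7.60), MEF2C (8.38), MYT1L (7.79) and LMO4 (8.83), and high in CDH1 (4.88, others up to 4.39). By list it was the lowest brain array in 26 of 29 neuronal genes and the highest in 14 of 16 astrocyte, 13 of 16 oligodendrocyte and 6 of 8 oligodendrocyte precursor genes, where chance gives 20%. It was also highest in 15 of 20 endothelial, 14 of 22 immediate early and stress and 12 of 17 urea and amino acid genes, so the pattern is not limited to glia. Its median log2 distance from the other brain arrays was 1.42, 0.924 and 0.752 in the glial lists and 0.436, 0.435 and 0.235 in those. GFAP stood at 12.59 (others up to 11.64), GJA1 at 10.92, SLC1A3 at 11.57 and MBP at 13.59, without passing Dixon's limit. It also had the largest 3′ minus 5′ difference of GAPDH in brain, 1.16.

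Liver 2, the liver array with the lowest mean correlation (0.884), was low in AHSG (10.52), SLC27A5 (8.92), AGXT (9.13), PCK1 (5.93, others from 9.37) and CEBPA (9.73). Without passing Dixon's limit, it was also the lowest liver array in ALB (12.84), APOC3 (12.19), APOA2 (10.92), SERPINA1 (12.24) and ORM1 (10.21). The same held for ADH1B (10.03), APOH (10.33), CYP2E1 (12.61) and CYP2C8 (10.19). Liver 5 was low in KDR (4.97), brain 2 in SGCE (6.18), and brain 3 was high in HP (5.27). Among the tumors, tumor 3 had a low 3′ minus 5′ difference of GAPDH (0.468), low CCL23 (2.94) and ETFB (4.89, others from 7.94) and high MEST (9.62), and tumor 4 had low CXCL3 (7.28, others from 9.40). Normal colon 4 was high in SFRP1 (7.71).

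Probe sets without a gene symbol were not part of the comparisons. In limma, with the array's own control probe sets left out, 16 of 11721 were higher and 16 lower in colon tumor, and 236 of 2107 were higher and 350 lower in brain than in liver.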

How the results depend on the processing

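Chosen after the data were seen were the fits with normal colon 1 and 2 averaged, without liver 2 and 3 and with the GAPDH covariate, and the matched lists for the overlap alternatives. With the covariate 87.4% of the 4570 genes kept their direction between brain and liver, and 7 of 116 named genes did not; with 1 array left out and with the block 0 named genes changed direction. For colon tumor against normal colon, 275 genes were higher with probe sets that lack shared-probe suffixes, where fewer genes are tested, 3 were higher and 10 lower with a change over 2-fold required, and 127 were higher and 153 lower with normal colon 1 and 2 averaged, where fewer arrays are fitted. The covariate, which separates the colon groups, left 19 higher and 33 lower. Leaving out 1 array gave 87 (without normal colon 2) to 608 (without normal colon 3) higher and 123 to 754 lower genes for the same arrays; the cause was not tested. For brain against liver, the plain probe sets gave 1683 higher genes, a required 2-fold change 717 higher and 411 lower, and the covariate 802 higher and 759 lower. Leaving out 1 array there gave 2204 to 2670 higher and 1585 to 2221 lower, and leaving out liver 2 and 3 together gave 2715 and 2202.

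With an estimated correlation 2 colon lists and 0 tissue lists were called, and fry called 11 colon and 21 tissue lists; the list counts ranged from 15 to 19 and from 18 to 21 with 1 array left out. The odds ratio of the overlap was 1.7 with a change over 2-fold required as well and 1.28 with the mean of all probe sets, both at an unadjusted Fisher p under 0.05, and 1.12 (without tumor 4) to 1.6 (without normal colon 2) with 1 colon array left out; the cause was not tested.

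With the replicate number as a block, which pairs samples of the same number, 380 genes were higher and 340 lower in tumor. These were only in part the same genes: 281 of the 483 higher and 262 of the 394 lower genes stayed called. The other genes called with the block were not called without it. In brain 2477 were higher and 1933 lower with the block. Here 2397 of the 2551 higher and 1818 of the 2019 lower genes stayed called. The block left 19 colon and 21 tissue lists called, and the odds ratio of the overlap was 1.2 (unadjusted Fisher p = 0.0405). Of the 67 named colon genes past the threshold 14 lost their call and CD14 gained one; apart from these, from the list counts and list calls given with their values, and from the overlap, the block changed no other call of a named gene or list. Of 116 named brain and liver genes 0 lost their call with the block, and 0 to 6 with 1 array left out. Repeated quantile normalization (666 higher and 455 lower in tumor), median centring (385 and 334), the filter on low values (581 and 494), the mean of all probe sets (428 and 345) and the trended robust prior (429 and 429) stayed within 1.5 times the counts given. The planned fit of all groups of a table together was not run, because no other group shares the normalization of either set of arrays, and the alternatives for brain or liver against normal colon were not run. Signal over background limits what can be seen of genes near the floor, whose folds are compressed.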

Other observations

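Families of at least 10 genes that share a symbol root were formed after the data were seen, 249 on the colon arrays and 142 on the brain and liver arrays, and tested with camera. Genes of the large subunit of the mitochondrial ribosome (MRPL) had 10 of 50 higher in colon tumor, 0 lower and a median log2 change of 0.50 (camera adjusted p = 1.24e-12, adjusted p = 0.761 with an estimated correlation). MRPL3 had a log2 change of 0.82 ± 0.11 (SE, n = 4 and 4, limma adjusted p = 0.00857). The small subunit (MRPS) had 4 of 27 higher with a median of 0.49 (camera adjusted p = 1.69e-06, adjusted p = 0.761 with an estimated correlation). Nuclear pore genes (NUP) had 4 of 26 higher with a median of 0.56 (camera adjusted p = 3.3e-05, adjusted p = 0.761 with an estimated correlation), among them NUP107 at 0.94 ± 0.18. Metallothionein genes (MT), which encode metal-binding proteins, had a median of -1.45 although 0 of 10 passed in limma (8 at an unadjusted p under 0.05; camera adjusted p = 0.000156, adjusted p = 0.761 with an estimated correlation). MT1M stood at -3.15 ± 0.75 (adjusted p = 0.0541) and MT2A at -1.51 ± 0.37 (adjusted p = 0.0577). The genes named here were chosen after their values were seen, and the medians kept their sign with repeated quantile normalization and with centred medians.

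Between brain and liver, genes with the root ATP, which include subunits of the vacuolar proton pump and of ATP synthase, were higher in brain in 37 of 69 cases and lower in 4, with a median log2 change of 1.04 (camera adjusted p = 0.000623, adjusted p = 0.997 with an estimated correlation). Genes of vacuolar protein sorting (VPS) had 16 of 28 higher and 1 lower (camera adjusted p = 0.0169, adjusted p = 0.997 with an estimated correlation). Aldehyde dehydrogenases (ALDH) had 9 of 17 lower in brain with a median of -1.39 (camera adjusted p = 0.000876, adjusted p = 0.997 with an estimated correlation), and hydroxysteroid dehydrogenases (HSD) 8 of 15 lower (camera adjusted p = 0.00264, adjusted p = 0.997 with an estimated correlation). These medians also kept their sign under both scalings.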
